A study of Mus musculus with 16 samples.

How the data were processed

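RNA was measured in the striatum of 8 adult C57BL/6N mice. Each mouse had received a RiboTag virus, which puts a hemagglutinin-tagged copy of the ribosomal protein Rpl22 into astrocytes. A second virus carried either a control protein (4 mice, called control mice) or hPMCA2w/b (4 mice, called PMCA mice), a human plasma membrane calcium pump that lowers calcium signals. From each mouse the RNA of the cleared lysate (input) and the RNA bound to the tagged astrocyte ribosomes (precipitate, or IP) were sequenced separately, which gives 16 libraries in 4 groups of 4. Per the labels' protocols, RNA was purified with an RNeasy kit, and stranded libraries were made with a TruSeq kit after ribosomal RNA removal with RiboZero Gold and read on an Illumina HiSeq instrument.

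Per the submitters' processing notes, the tools were STAR, HTSeq, edgeR and limma and the genome build was mm10. Their versions, roles and settings, the gene annotation, and whether counting used the strand are not given in the sources used here. The deposited values are log2 CPM for 20730 genes in each library, with 1 lowest value of -7.47 shared by all 16 libraries. That pattern, and the values of low genes, gave the prior count (0.25 on average) and the effective library sizes. When the log2 scale and the prior count were undone, the value of every gene in every library was a whole number of reads within a tolerance of 0.001, and the largest deviation was 2e-08. Library totals therefore could be computed, and the scaling factor that the authors applied to each library was read from the ratio of the effective size to the total.

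Of the gene names, 19546 matched a symbol of the RefSeq annotation of the GRCm38.p6 assembly, 1070 matched only a synonym and 114 matched neither. Among the names, 26 looked like dates and 2 were given to more than 1 gene. Positions are those of that annotation, whose coordinates are those of mm10. Mitochondrially encoded genes were not among the genes analysed here, so the list of mitochondrially encoded proteins had 0 members. Dopamine receptor D1 is listed under its older symbol Drd1a. Where reads of near-identical genes or of overlapping genes on opposite strands were counted is not known, so values of gene families such as Serpina3, Ly6, Pir and the interferon-inducible Mndal family, and of pairs such as Xist and Tsix, are uncertain to that extent.

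The design had assumed read counts and a quasi-likelihood test, which was not run. Because the deposited unit is a log2 value, the test was changed to limma (version 3.58.1 in R 4.3.3): a linear model per gene on the deposited log2 CPM with empirical Bayes moderation and a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Genes entered a comparison with at least 10 reads, in a library of median effective size, in at least 4 of its libraries, and at least 15 reads over all of them. The groups, comparisons, gene lists, naming rule and most alternative settings were chosen before the data were examined. Settings and gene sets added later are named as such.

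5 comparisons were fitted: PMCA against control mice in the 8 IP libraries, the same in the 8 inputs, IP against input in control mice and in PMCA mice, and the difference of the PMCA effect between IP and input over all 16 libraries. Astrocyte-enriched genes were defined as genes with a log2 fold of at least 1 for IP over input, averaged over both treatments, and an adjusted p under the threshold, and their adjusted p for the PMCA effect was recomputed over these genes alone. Input and IP of 1 mouse share an animal. Over 13123 genes, the deviations of the 2 libraries of 1 mouse from their group means correlated with r between 0.24 and 0.68 (8 pairs), against -0.47 to 0.20 between different mice of 1 group (24 pairs), and each of the 8 inputs correlated best with its own IP. The pairing therefore rests on the labels and is visible in the data, and the fit with the animal as a block was an alternative for each comparison across fractions. Animal numbers fall in 2 sets, a lower one (control 1 to 3 and PMCA 1 and 2) and a higher one (control 4 and PMCA 3 and 4), which were tried as a block. Control 4 carries different animal numbers in its title and its source name, and both placements were tried. Replicates of a group correlated with r between 0.982 and 0.996 across genes and differed by more than sampling noise in every pair (chi-square per degree of freedom 4.7 to 104), so each was counted as a separate sample.

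The 35 gene lists cover markers of astrocytes, neurons, striatal projection neurons, direct-pathway and indirect-pathway neurons, striatal interneurons, oligodendrocytes, their precursors, microglia, endothelial cells, mural cells, leptomeningeal fibroblasts, ependymal and choroid plexus cells and blood; genes of pan-reactive, A1 reactive and A2 reactive astrocytes, the interferon response, GABA handling, glutamate handling, potassium, water and gap junctions, calcium pumps, channels and stores, astrocyte G-protein-coupled receptors, synapse-acting secreted factors and matrix, cholesterol synthesis, immediate early genes, glycolysis and lactate, the unfolded protein response, clock genes, the glucocorticoid response, nuclear noncoding RNA and sex linkage; and ribosomal proteins, the nuclear-encoded respiratory chain and mitochondrially encoded proteins. Per list, members past the threshold were counted over all genes tested and with p adjusted over the list alone. Lists were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01 and again with the correlation estimated from the residuals, and with fry, which asks whether a list's genes move on balance one way and does not compare them with other genes. The p-values of lists were adjusted over the 33 lists with at least 2 genes tested. Rpl22 was left out of the ribosomal protein list.

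Named genes were Atp2b2 and Rpl22 first, then per comparison the 10 highest and the 10 lowest log2 folds among genes past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the groups (not applicable to the difference of effects), leaving out predicted and Riken genes; per list the 2 to 4 called members of largest change, or the 2 of smallest p where none was called; and a fixed set of astrocyte, neuron and other markers. Some genes that fit the rule are not reported here. Genes outside that rule are said to have been chosen after their values were seen.

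The steps were tested on simulated data in which 100 genes changed by 1.5-fold and 100 by 2-fold. Of these, limma recovered 65 and 81 for PMCA against control in IP (15882 genes), 70 and 81 in input (16408 genes), 56 and 79 for IP against input in control mice (16201 genes), 61 and 75 in PMCA mice (16443 genes), and 47 and 71 for the difference of effects (16824 genes). Between 4.9% and 10.6% of calls were genes simulated as unchanged. A list shifted in the simulation was called in each comparison, and 0 of 33 unshifted lists were. Genes varied independently in the simulation, so it does not show how often lists of correlated genes are called falsely. Alternatives were size factors by relative log expression, total reads without scaling factors, other filters, limma-voom on the recovered reads, robust moderation, all 16 libraries in 1 fit, blocks for the animal, the number set and sex, covariates for the purity of the precipitate and for microglial RNA, and leaving out each animal in turn. Read totals ranged from 32.3 to 58.5 M. Many changes of 1.5-fold were therefore missed with 4 libraries per group, most of all for the difference of effects, and p-values rest on the spread between 4 animals.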

Results

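Striatal RNA was measured in 8 mice, 4 that expressed a control protein and 4 that expressed the calcium pump hPMCA2w/b. Each mouse gave an input library of the whole lysate and an IP library of RNA on tagged astrocyte ribosomes. Input libraries held 33.1 to 40.2 M reads in control mice (mean 36.6 ± 4.04 M, SD, n = 4) and 32.3 to 40.9 M in PMCA mice (37.6 ± 3.84). IP libraries held more, 46.8 to 58.5 M in control mice (53.4 ± 4.92) and 48.1 to 55.1 M in PMCA mice (52.2 ± 3.08). The authors' scaling factors were 1.10 to 1.12 in the inputs and 0.89 to 0.92 in the IP libraries. The 10 genes with most reads took 1.93% to 2.43% of the reads of an input and 6.03% to 8.88% of those of an IP. The first principal component held 87.4% of the variance and parted IP from input, and the next held 4.42%. The animals' sex is not given in the labels used here. Xist, which silences an X chromosome in female cells, lay at 4.98 to 9.11 log2 CPM in the libraries of control 4 and PMCA 3, whose Ddx3y, a Y-linked gene, lay at -3.72 to -1.64. In the other 6 mice Xist lay at -2.55 to -0.09 and Ddx3y at 6.35 to 7.25. One such mouse was therefore in each treatment group.

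**Figure D1:**
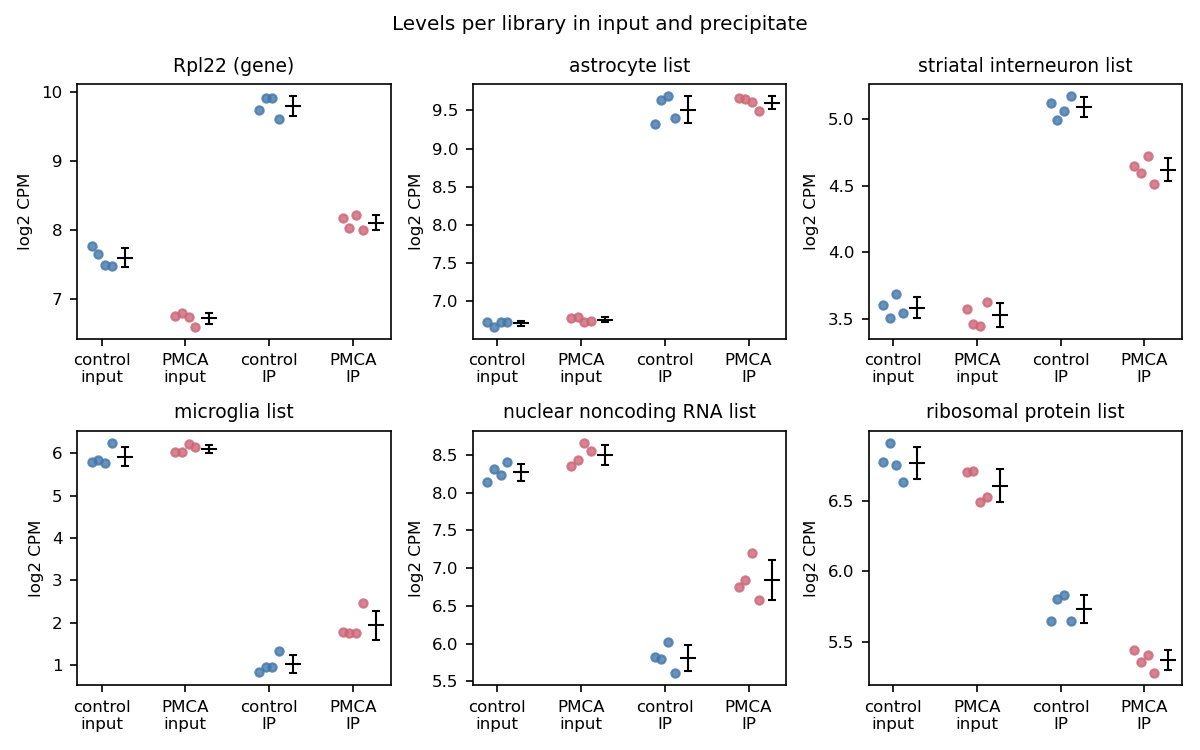
Level in log2 CPM of Rpl22 and of 5 gene lists (mean over list members) in each of 16 libraries, with points for the 4 libraries of a group and a bar for their mean ± SD. Rpl22 lay at 9.80 in control IP and 8.11 in PMCA IP, and the microglia list at 1.02 and 1.94.

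The genes that the viruses carry were examined first. Rpl22 (chromosome 4, 152324436 to 152334082, mm10), the ribosomal protein that carries the tag, was lower in PMCA mice. Its level was 9.80 ± 0.15 log2 CPM (SD, n = 4) in control IP and 8.11 ± 0.11 in PMCA IP, so it fell by 1.69 on the log2 scale (SE 0.089, adjusted p = 1.92e-05, limma), and all 4 PMCA libraries lay below all 4 control libraries. In input it fell from 7.60 ± 0.14 to 6.72 ± 0.086 (log2 fold -0.88, SE 0.066, adjusted p = 0.000489). Reads of the tagged copy and of the mouse's own gene were counted together. The level of Rpl22 thus followed the treatment in both fractions. In no comparison of PMCA with control mice can an effect of the pump be told apart from one of a lower Rpl22 level. Atp2b2 (chromosome 6, 113743831 to 114042613, mm10), the mouse gene for the pump PMCA2, lay at 9.52 ± 0.27 in control IP and 9.87 ± 0.20 in PMCA IP (log2 fold 0.35, SE 0.14, adjusted p = 0.113), and at 10.29 ± 0.051 and 10.42 ± 0.068 in input (0.13, SE 0.044, adjusted p = 0.153). The IP difference passed without control 1 (0.47, adjusted p = 0.029) and with a purity covariate (0.72, adjusted p = 0.0072), which itself follows the treatment in part. How far reads of the human transgene were counted under Atp2b2 is not given in the sources used here.

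The comparison of IP with input in control mice asked how far the precipitate was enriched for astrocyte RNA. All 41 astrocyte markers rose (median log2 fold 2.78). They were led by Atp1b2, a sodium pump subunit (4.06, SE 0.095), Slc1a2, a glutamate transporter (3.91, SE 0.16), Sox9, an astrocyte transcription factor (3.72, SE 0.086), and Kcnj10, an inward-rectifier potassium channel (3.59, SE 0.10; n = 4 and 4). Microglial RNA was the most depleted of the cell types listed, with 19 of 20 markers lower (median -5.54). Ctss, a lysosomal protease, fell by 6.45 (SE 0.22), Tyrobp, a receptor adaptor, by 6.39 (SE 0.27) and C1qb, a complement subunit, by 6.31 (SE 0.19) on the log2 scale. Rmrp, the nuclear-encoded RNA of an RNA-processing enzyme, fell by 6.98 (SE 0.11).

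Among other astrocyte genes, Aldh1l1 rose by 3.18 (SE 0.097), Gfap by 3.38 (SE 0.21), Aqp4 by 3.23, Slc1a3 by 3.08, Gja1 by 3.06, Slc6a11 by 2.89, Itpr2 by 2.49 and S100b by 1.84 on the log2 scale. The genes of largest rise also included Gli2 (3.93, SE 0.22), Tead1 (3.79, SE 0.080), Gpc4 (3.59, SE 0.13), A2m (3.59, SE 0.36), Creb3l1 (3.58, SE 0.40) and Dthd1 (3.76, SE 0.70). Those of largest fall included Ly6c2 (-7.32, SE 0.93), Ccl12 (-6.98, SE 0.54), Cd79b (-6.91, SE 0.81), Fcgr4 (-6.54, SE 0.40), Ccl9 (-6.37, SE 0.77) and the GABA transporter gene Slc6a13 (-6.26, SE 0.76). Ly6c2, Ccl12 and Ccl9 belong to families of similar sequence, and their values are uncertain to that extent. In control IP the means of Ly6c2, Ccl12, Cd79b, Fcgr4, Ccl9 and Slc6a13 lay between -5.84 and -3.61 log2 CPM. That is toward the lowest value of -7.47, so the size of these falls is uncertain. Endothelial markers fell in 15 of 16 cases (median -3.87, Cldn5 -4.36, SE 0.30), and Cx3cr1 of microglia fell by 5.42 (SE 0.16). Rpl22 rose by 2.20 (SE 0.090) and Atp2b2 fell by 0.77 (SE 0.12).

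Neuronal RNA was depleted less, and in part not at all. All 16 markers of striatal projection neurons fell (median -1.55), with Ppp1r1b at -1.52 (SE 0.14), and so did all 6 of the indirect pathway (-1.72, Drd2 -1.31) and 6 of 8 of the direct pathway (-1.41, Drd1a -1.83), of which 2 rose. Of 26 general neuronal markers 16 fell and 4 rose (median -0.36, Rbfox3 -1.32, SE 0.10). In contrast, 12 of 13 markers of striatal interneurons rose and 1 fell (median 1.62), among them Nos1 for nitric oxide synthase (3.48), Chat for acetylcholine synthesis (2.50) and Slc5a7 for choline uptake (2.31). Oligodendrocyte markers rose in 11 of 20 cases and fell in 1 (median 0.56), and Mbp did not pass (-0.15, SE 0.21, adjusted p = 0.536). Of the precursor markers 8 of 11 rose and 2 fell (0.64). Of mural markers 3 of 11 rose and 7 fell (-1.69), of leptomeningeal markers 2 of 7 rose and 5 fell (-2.63). Of ependymal markers 6 of 9 rose and 2 fell (2.14), and the blood gene tested, Alas2, fell (-2.33).

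By function, rises were counted for 12 of 13 pan-reactive genes (median 2.71), 9 of 12 A1 genes (1.83, 3 fell), 7 of 11 A2 genes (0.97, 2 fell), 15 of 18 interferon genes (1.66, 1 fell), 10 of 13 genes of GABA handling (1.304, 3 fell) and 8 of 11 of glutamate handling (2.11, 2 fell). They were also counted for 16 of 17 of potassium, water and gap junctions (2.55), 15 of 17 synapse-acting factors (2.25, 1 fell), 22 of 22 genes of cholesterol synthesis (1.52), 21 of 23 of glycolysis (0.85, 2 fell) and 15 of 23 astrocyte receptors (0.75, 6 fell). Falls were counted for 16 of 23 immediate early genes (-1.01, 3 rose), 7 of 7 nuclear noncoding RNAs (-2.59), and 76 of 82 ribosomal proteins (-1.12, 3 rose). Calcium genes went both ways (14 of 37 rose and 19 fell, median -0.27), as did the unfolded protein response (12 and 4 of 20, 0.32), the glucocorticoid response (6 and 2 of 11, 0.56) and the respiratory chain (29 and 17 of 77, median 0.06). Of the clock genes 7 of 16 rose and 6 fell, with a median of 0.03 and a mean and test that pointed down, and no sex-linked gene passed (0 of 5, none at an unadjusted p under 0.05 in limma).

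In the test, 12457 of 16072 genes passed, 6285 higher and 6172 lower in IP, with 2675 and 2784 of these changed at least 2-fold. With total reads and no scaling factors the calls split 4486 to 8417, since the median of all genes then shifted by -0.28, so all changes are relative to the scaling. The camera test placed 19 lists apart from other genes, among them the astrocyte (adjusted p = 6.19e-17), microglia (5.05e-10), endothelial (1.2e-06), interneuron (0.000356) and ribosomal protein lists (1.22e-15). None passed with an estimated correlation, where the adjusted p was at least 0.321, while fry's adjusted p was 3.42e-07 for the astrocyte and 2.21e-07 for the microglia list. The neuron list had an adjusted p of 0.027, and 0.647 with an estimated correlation.

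The same comparison in PMCA mice gave a similar picture. All 41 astrocyte markers rose (median 2.82), with Atp1b2 at 4.60 (SE 0.12), Slc1a2 at 4.00 (SE 0.12), Sox9 at 3.98 (SE 0.083), Kcnj10 at 3.96 (SE 0.077), Gfap at 3.61 (SE 0.11) and Aldh1l1 at 3.34 (SE 0.057; n = 4 and 4). Acsm5, a mitochondrial acyl-CoA ligase (4.27, SE 0.37), Ston1 (4.02, SE 0.19), Gpc4 (3.97, SE 0.096), Gli2 (3.88, SE 0.20), Tead1 (3.87, SE 0.13) and the transcription factor Tfcp2l1 (3.85, SE 0.061) completed the 10 genes of largest rise. Aqp4 rose by 3.12, Gja1 by 3.04, Slc1a3 by 2.999, Slc6a11 by 2.82, Itpr2 by 2.38 and S100b by 2.13, and the tagged gene Rpl22 rose by 1.39 (SE 0.066).

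Microglial markers were lower in 19 of 20 cases (median -4.41). These included Ctss (-6.05, SE 0.12), C1qb (-5.94, SE 0.11), Tyrobp (-5.73), C1qc (-5.71) and Cx3cr1 (-4.05, SE 0.57). Saa3 (-6.22, SE 0.78), the small nucleolar RNA Snora74a (-6.08, SE 0.60), Rmrp (-5.98, SE 0.16), Ccl6 (-5.78), Fcgr4 (-5.66) and Igj (-5.61) were the other genes of largest fall, of which Saa3 and Ccl6 have close paralogs. In PMCA IP Saa3 (-5.03 log2 CPM) and Ccl6 (-3.77) also lay toward the lowest value, so the size of their falls is uncertain. Endothelial markers fell in 14 of 16 cases and rose in 1 (-3.22, Cldn5 -4.05). Projection neuron markers fell in 16 of 16 (-1.57, Ppp1r1b -1.57), those of the indirect pathway in 6 of 6 (-1.91, Drd2 -1.09) and of the direct pathway in 6 of 8 with 2 higher (-1.55, Drd1a -1.93). Of the neuron list 19 of 26 fell and 3 rose (-0.73, Rbfox3 -1.39), and 9 of 13 interneuron markers rose and 2 fell (1.28, Nos1 3.01, Chat 1.98). Oligodendrocyte markers rose in 16 of 20 cases (0.65), Mbp not passing (0.12, SE 0.10, adjusted p = 0.294).

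Of the other lists, cholesterol synthesis rose in 22 of 22 genes (median 1.44), potassium, water and gap junctions in 16 of 17 (2.66), and nuclear noncoding RNA fell in 7 of 7 (-1.51) and ribosomal proteins in 78 of 82 (-1.35, 3 rose). The test passed 12551 of 16345 genes, 6121 higher and 6430 lower (2695 and 2760 at least 2-fold), or 4283 and 8908 with total reads and a median shifted by -0.35. Camera placed 22 lists apart, with an adjusted p of 4.64e-19 for the astrocyte list and 1.29e-08 for microglia. With an estimated correlation the smallest adjusted p was 0.133. The A1 list (0.0376) was not called without PMCA 4 (0.054). Across genes tested in both, 5605 were higher in both treatments against 2386 for independent lists, 5452 were lower in both against 2411, and the folds correlated with r = 0.959 across genes, which are not independent replicates.

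**Figure D2:**
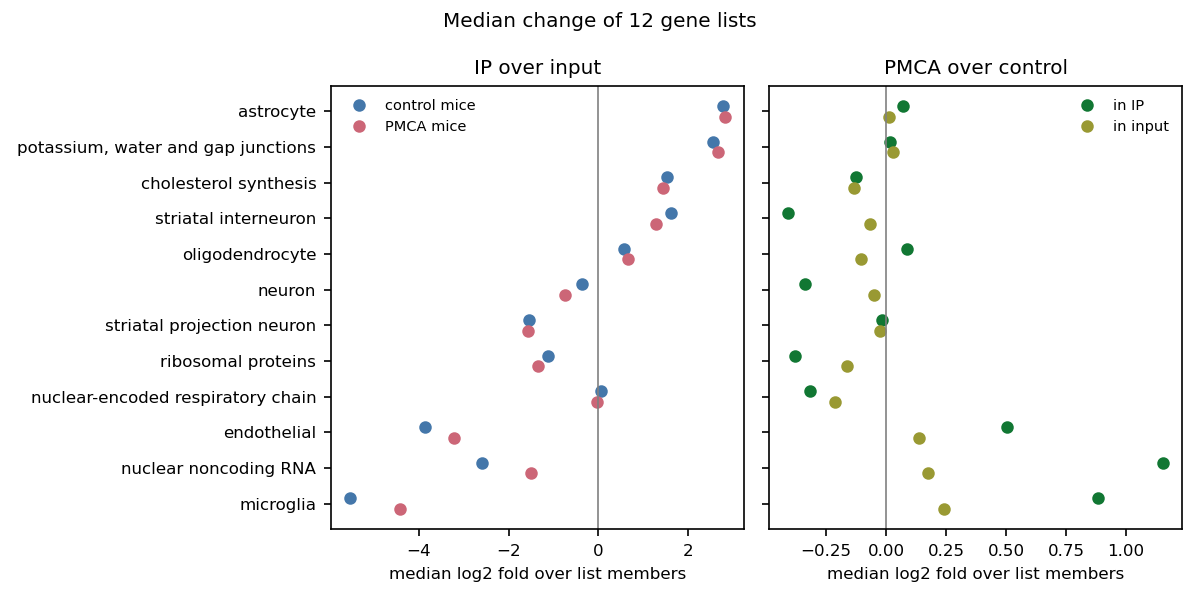
Median log2 fold over the members of 12 gene lists, on the left for IP over input in control and PMCA mice, on the right for PMCA over control in IP and in input. The nuclear noncoding RNA list lay at 1.15 and the ribosomal protein list at -0.38 for PMCA over control in IP.

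The comparison of PMCA with control mice in IP asked what differed in the precipitated RNA between the treatments, which also differed in Rpl22. Nuclear noncoding RNA was higher: all 7 transcripts rose (median log2 fold 1.15), among them Snhg11 (1.38, SE 0.16), Meg3 (1.21, SE 0.14) and Malat1, a speckle RNA (1.15, SE 0.19; n = 4 and 4). Transcripts of ribosomal proteins were lower in 65 of 81 cases (median -0.38, Rps27l -0.71, Rps19 -0.65, Rps26 -0.55), as were 53 of 77 of the respiratory chain (median -0.32, Cox6a2 -0.85, Cox6b2 -0.68, Ndufb6 -0.51). Microglial markers rose in 10 of 20 cases, with Itgam, an integrin, at 1.58 (SE 0.23) and Csf1r, a growth factor receptor, at 1.16 (SE 0.17). Interneuron markers fell in 8 of 13 cases, with Pvalb, a calcium buffer, at -1.38 (SE 0.11) and Pthlh, a peptide hormone, at -1.01 (SE 0.12). Adjusted over the list alone, 7 nuclear noncoding RNAs and 16 microglial markers (median 0.88) were higher, and 76 ribosomal protein, 64 respiratory chain and 9 interneuron transcripts (median -0.41) were lower.

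Among the largest falls were those of Gdf15, a stress-induced cytokine (-2.91, SE 0.16, adjusted p = 1.92e-05), Spp1, the matrix protein osteopontin (-2.16, SE 0.13, 3.04e-05), Sgca (-2.07, SE 0.17), Ckap2 (-1.98, SE 0.10), the chemokine Cxcl9 (-1.84, SE 0.26), Avil (-1.72, SE 0.10), Vtn, the matrix protein vitronectin (-1.64, SE 0.17), and the chemokine Cxcl5 (-1.64, SE 0.21). The largest rises were in genes of low level, 1.07 to 1.93 CPM on average, several of them leukocyte receptors. They included Csf2rb, a cytokine receptor chain (2.45, SE 0.45, adjusted p = 0.00689), Klk8, a protease (2.42, SE 0.47, 0.00853), Serpina3i (2.17, SE 0.39), Myo1f (2.15, SE 0.30), Cd33 (2.08, SE 0.19, 0.000562), Gdap10 (1.99, SE 0.32), Cd84 (1.91, SE 0.32), Havcr2 (1.89, SE 0.54, 0.0349) and Pram1 (1.88, SE 0.19). In control mice all of these but Serpina3i lay lower in IP than in input, such as Myo1f (-1.14 against 3.84 log2 CPM) and Cd84 (-1.01 against 3.35). In PMCA mice all but Serpina3i and Klk8 still did, such as Myo1f (1.01 against 4.38) and Cd84 (0.90 against 4.13). Csf2rb and Serpina3i have near-identical neighbours and are uncertain to that extent. Havcr2 did not pass without control 1 (adjusted p = 0.068), control 2 (0.082), control 4 (0.073) or PMCA 2 (0.056).

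Among astrocyte genes 4 of 41 markers rose and 3 fell (5 and 4 adjusted over the list alone, median 0.07). Atp1b2 (0.67, SE 0.13), Kcnj10 (0.54, SE 0.11, adjusted p = 0.0113), Sox9 (0.49, SE 0.079) and Aldh1l1 (0.44, SE 0.085) rose, and Agt, angiotensinogen (-0.69, SE 0.15), Slc25a18 (-0.58, SE 0.089) and Cldn10 (-0.34, SE 0.10) fell. Calcium genes changed in 5 of 37 cases: Ryr3 (0.64, SE 0.15) and Itpr2 (0.39, SE 0.079, adjusted p = 0.0104), release channels of the endoplasmic reticulum, Tpcn1 (0.42) and Orai3 (0.26) rose and Calm2 (-0.42) fell (3 and 1 adjusted over the list alone). The median of that list was -0.06 and its mean 0.00085. Gfap, a filament protein of reactive astrocytes, lay at 0.59 (SE 0.19, adjusted p = 0.0527) and passed without control 4 (0.71, adjusted p = 0.033). Slc1a2 (0.40, SE 0.22, 0.223) and the GABA transporter gene Slc6a11 (-0.10, SE 0.094, 0.488) did not pass.

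Of genes of reactive astrocytes, Serpina3n (1.01) and Aspg (0.69) rose and Hspb1 (-0.83) fell among 13 pan-reactive genes (6 and 1 adjusted over the list alone, median 0.45). Srgn (0.99) and Ggta1 (0.35) rose among 12 A1 genes (2 and 0, median 0.30), and Emp1 (0.94) rose among 11 A2 genes (1 and 0, median 0.19). Thbs2 (0.47), Ncan (0.40) and Gpc4 (0.38) rose among 17 synapse-acting factors (7 adjusted over the list alone, median 0.25). In glycolysis 8 of 23 genes fell, among them Ldha (-0.39), Pgam1 (-0.38) and Gpi1 (-0.33), and 2 rose, Hk2, a hexokinase (1.06, SE 0.17), and Gys1 (0.26), with 2 and 9 adjusted over the list alone and a median of -0.15. Of the unfolded protein response 4 of 20 genes fell (5 adjusted over the list alone, median -0.13), with Asns at -0.58, Herpud1 at -0.44, Hspa5 at -0.31 and Atf4 at -0.30.

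Among other cells' markers, 16 of 26 of the neuron list fell (18 adjusted over the list alone, median -0.34), with Nefh, a neurofilament, at -0.86 (SE 0.088), Gad1 at -0.65 and the vesicular GABA transporter Slc32a1 at -0.63. Projection neurons had 1 lower of 16 (0 adjusted over the list alone, median -0.02), the direct pathway 1 higher of 8 (Eya1 0.39, median -0.19) and the indirect pathway 1 lower of 6 (Gpr6 -0.63, median -0.09). Endothelial markers rose in 5 of 15 cases and fell in 1 (the same adjusted over the list alone, median 0.50), with Ly6a at 1.08, Ly6c1 at 1.08, Tek at 0.98 and Itm2a at -0.65, the Ly6 pair being uncertain. Of 9 mural markers Myh11 (0.97) and Pdgfrb (0.43) rose and Vtn and Rgs5 (-0.66) fell (2 and 3 adjusted over the list alone, median -0.11). Of 5 leptomeningeal markers Lum (1.45), Col1a1 (0.79) and Col1a2 (0.67) rose and Igf2 (-1.56, SE 0.14) fell (4 and 1, median 0.67), and Alas2 of blood rose (1.27). No marker passed, over all genes or over the list alone, for oligodendrocytes (0 of 20, 1 at an unadjusted p under 0.05 in limma, Myrf 0.71, adjusted p = 0.0543), their precursors (0 of 11, 1 unadjusted, Pdgfra -0.39, adjusted p = 0.131) or ependymal cells (0 of 9, 3 unadjusted, Ttr -2.28, adjusted p = 0.0543, median -0.37).

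In the remaining lists few genes passed. Irf9 (-0.39) fell among 18 interferon genes (median -0.19), Aldh1a1 (-0.50) among 12 of GABA handling (-0.07) and Got1 (-0.55) among 11 of glutamate handling (median 0.05, mean and test downward). Falls were also seen for Junb (-0.46) and Btg2 (-0.29) among 23 immediate early genes (-0.02), and Cdkn1a (-0.75) among 11 glucocorticoid genes (-0.08). Atp1b2 and Kcnj10 rose among 17 of potassium, water and gap junctions (0.02). Ednra (0.58) rose and P2ry1 (-0.57) and Cnr1 (-0.36) fell among 23 astrocyte receptors (-0.05), and Srebf2 (0.31) rose and Fdps (-0.36) and Fdft1 (-0.29) fell among 22 genes of cholesterol synthesis (-0.13). Among clock genes 0 of 16 passed (3 at an unadjusted p under 0.05, Arntl -0.17, median 0.08), and among sex-linked genes 0 of 5 (0 unadjusted, Xist 2.23, SE 2.21).

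In the limma test 3088 of 15748 genes passed, 1503 higher and 1585 lower, with 387 and 57 changed at least 2-fold. The count fell to 1710 without control 2, 2047 without control 3, 1980 without PMCA 2 and 1719 without PMCA 3, while all 16 libraries in 1 fit gave 4894. It was 1347 with the purity covariate, 1699 with the number set as a block and control 4 placed by its source name, and, both chosen after seeing the data, 1243 without control 4 and PMCA 3 and 395 with the microglial level as a covariate. The microglia list lay at 0.83 to 1.34 log2 CPM in control IP and 1.75 to 2.46 in PMCA IP. Purity, the neuron minus the astrocyte list level, also follows the treatment in part (neuron list 7.62 to 7.98 and 7.38 to 7.53). Both covariates can thus take out an effect of treatment itself, so results with them do not tell its source. Camera called 11 lists: higher were nuclear noncoding RNA (adjusted p = 8.2e-07), microglia (8.2e-07), synapse-acting factors (0.0221), A1 (0.0229) and endothelial cells (0.0229). Lower were ribosomal proteins (3.05e-26), respiratory chain (3.07e-21), neurons (2.94e-07), interneurons (5.18e-06), unfolded protein response (0.0186) and glycolysis (0.0411). None kept the call with an estimated correlation: the adjusted p was 0.324 for interneurons, 0.505 for nuclear noncoding RNA, microglia, endothelial cells, ribosomal proteins and respiratory chain, 0.567 for neurons, 0.601 for synapse-acting factors and the unfolded protein response, 0.664 for A1 and 0.905 for glycolysis. By fry, which asks only for a shift on balance, adjusted p was 0.000828 for interneurons, 0.00843 for nuclear noncoding RNA, 0.00886 for microglia, ribosomal proteins, respiratory chain and leptomeningeal cells, 0.0182 for neurons and endothelial cells and 0.0449 for glycolysis. Glycolysis was not called without control 2 (0.055), control 3 (0.094), control 4 (0.055) or PMCA 4 (0.12). A1 was not called without control 1 (0.12) or PMCA 4 (0.12), and with the microglial covariate its median turned to -0.51. The same loss of call was found for endothelial cells without PMCA 4 (0.091), synapse-acting factors without control 1 (0.066), and the unfolded protein response without control 4 (0.085). With the number set as a block and control 4 placed by its source name, A1 (0.226), endothelial cells (0.149) and glycolysis (0.12) were not called.

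Restricted to 2734 astrocyte-enriched genes, the test passed 510, of which 364 rose and 146 fell in PMCA mice, 26 and 15 of them at least 2-fold. Named genes that fell in this set included Gdf15 (-2.91), Sgca (-2.07), Ckap2 (-1.98), Avil (-1.72), Rpl22 (-1.69) and Cxcl5 (-1.64). Those that rose included Serpina3i (2.17), a gene of low level with near-identical neighbours, Atp1b2 (0.67), Kcnj10 (0.54), Sox9 (0.49) and Aldh1l1 (0.44). The median over enriched genes was 0.07 and 59.8% lay above 0, while the 3080 input-enriched genes had a median of 0.12. With a covariate for the purity of the precipitate, 81 rose and 176 fell, so the balance of directions turned. That covariate follows the treatment in part, so it can take out an effect of treatment itself. The count was 338 without control 2, 290 without PMCA 1 and 315 without PMCA 3.

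In input, which asked what differed between the treatments in the whole striatum, few genes passed. The largest rises included those of Ccl3 (log2 fold 1.55, SE 0.20, adjusted p = 0.0147) and Ccl4 (1.18, SE 0.21), chemokines, Clec7a, a fungal pattern receptor (1.13, SE 0.14, 0.0146), Fcgr2b, an antibody receptor (1.08, SE 0.18), and Gpnmb, a membrane glycoprotein of phagocytes (1.35, SE 0.23; n = 4 and 4). Cdkn1a, a cell cycle inhibitor (-0.81, SE 0.13, adjusted p = 0.0403), Ccng1, a cyclin (-0.46, SE 0.052, 0.00713), and Aldh1a1, an aldehyde dehydrogenase (-0.47, SE 0.053, 0.00713), fell. The glutamate transporters Slc1a3 (0.26, SE 0.039, adjusted p = 0.0344) and Slc1a2 (0.31, SE 0.058, 0.0485) rose.

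Pirb (1.18, SE 0.21), Nlrp1c-ps (1.17, SE 0.22), Fn1 (0.95, SE 0.15), Itga4 (0.91, SE 0.13) and Lrtm1 (0.89, SE 0.16) completed the largest rises. Cox6b2 (-1.09, SE 0.19), Mxra7 (-0.78, SE 0.082, adjusted p = 0.00713), Eda2r (-0.77, SE 0.12), Phlda3 (-0.62, SE 0.097), Igfbp2 (-0.45, SE 0.075) and Aen (-0.43, SE 0.074) completed the largest falls. Reads of Pirb, Nlrp1c-ps and the Ccl genes can be shared with near-identical genes. Itpr2 (0.49, SE 0.11, 0.077), Gfap (0.36, SE 0.16, 0.244), Kcnj10 (0.17, SE 0.069, 0.228) and Slc6a11 (-0.03, SE 0.078, 0.855) did not pass.

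The test passed 72 of 16306 genes, 59 higher and 13 lower, 10 and 1 of them at least 2-fold, and 3152 genes had an unadjusted p under 0.05. Each animal left out moved the count by more than 1.5 times: to 10 without control 1, 10 without control 2, 6 without control 3, 1350 without control 4, 5 without PMCA 1, 6 without PMCA 2, 5 without PMCA 3 and 33 without PMCA 4. With the animal-number set as a block it was 868 with control 4 placed by its title and 32 with control 4 placed by its source name. It was 786 with sex, read from Xist and Ddx3y, as a block and 490 without control 4 and PMCA 3, both chosen after seeing the data. The set of control 4 and PMCA 3 and 4 held 1 control mouse and was not fitted alone. Of 21 named genes past the threshold, 4 kept their call whichever animal was left out, Rpl22, Ccng1, Aldh1a1 and Mxra7. Without control 4 Gfap (0.54, adjusted p = 0.00637), Itpr2 (0.62, 0.000385) and Kcnj10 (0.22, 0.0452) passed.

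By list, camera called 13 in input while few single members passed. Higher were the A1 genes (median 0.37, adjusted p = 0.000514, 0 passing and 4 adjusted over the list alone, C3 1.34, adjusted p = 0.0669), microglia (0.24, 0.00112, 0 and 0), synapse-acting factors (0.15, 0.00265, 0 and 1), pan-reactive genes (0.42, 0.00966, 0 and 4, Serpina3n 0.997), leptomeningeal cells (0.28, 0.0219, 0 and 0) and nuclear noncoding RNA (0.17, 0.0258, 1 and 2, Kcnq1ot1 0.78). Lower were the respiratory chain (-0.21, 1.85e-22, 1 and 52 of 77), ribosomal proteins (-0.16, 4.74e-16, 0 and 3 of 82), cholesterol synthesis (-0.13, 0.000535, 0 and 3, Msmo1 -0.20), oligodendrocytes (-0.11, 0.0121, with 1 member higher adjusted over the list alone), glycolysis (-0.06, 0.0122, 1 and 1, Pgam1 -0.22), interferon genes (-0.21, 0.0219, 0 and 0) and neurons (-0.05, 0.0348, 0 and 0). With an estimated correlation none was called, with an adjusted p of 0.654 or 0.693 for each of them, and fry's adjusted p was at least 0.286. At an unadjusted p under 0.05, limma gave 5 A1 genes, 9 microglial markers, 6 synapse-acting factors, 9 pan-reactive genes, 3 leptomeningeal markers, 29 ribosomal proteins, 9 genes of cholesterol synthesis, 5 oligodendrocyte markers, 2 interferon genes and 9 neuronal markers.

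The A1 and pan-reactive levels in input also followed the animal numbers. The mean A1 level was 4.81 to 5.002 log2 CPM in control 1 to 3 and 5.57 in control 4, against 5.30 and 5.32 in PMCA 1 and 2 and 5.69 and 5.67 in PMCA 3 and 4, so control 4 lay above PMCA 1 and 2. The pan-reactive level of control 4 (3.35) likewise lay above those of PMCA 1 (2.96) and PMCA 2 (2.81), and above that of PMCA 3 (3.33). The microglia level of control 4 (6.25) lay above those of all 4 PMCA inputs (6.02 to 6.23). With the number set as a block the median of the A1 reactive astrocyte list in PMCA against control in input was 0.20 (adjusted p = 2.55e-06), or 0.15 (0.0243) with control 4 placed by its source name. In that placement the pan-reactive (adjusted p = 0.404), nuclear noncoding RNA (0.425), oligodendrocyte (0.355) and neuron lists (0.0699) were not called, and neurons were not called by title either (0.0787).

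Some list calls in input rested on single animals. Glycolysis was not called without PMCA 2 (0.0739) or control 4 (0.0923) and interferon without PMCA 1 (0.299), PMCA 2 (0.207) or control 4 (0.356). The same held for leptomeningeal cells without control 2 (0.0821) or PMCA 3 (0.0534), neurons without control 1 (0.23), control 3 (0.0937), PMCA 2 (0.157) or PMCA 3 (0.0614), nuclear noncoding RNA without control 1 (0.162) or PMCA 3 (0.0802), oligodendrocytes without control 4 (0.217) or PMCA 3 (0.054) and pan-reactive genes without control 1 (0.0531). Of astrocyte markers 2 of 41 rose, Slc1a2 and Slc1a3 (8 higher and 3 lower adjusted over the list alone, median 0.0099, camera's adjusted p = 0.147). For calcium genes 0 of 37 passed (10 at an unadjusted p under 0.05, 3 higher adjusted over the list alone, Ryr3 0.27, adjusted p = 0.0888), with a median of -0.0065 while mean and test pointed up. Interneuron markers, lower in IP, had a median of -0.07 in input with 0 of 13 passing (2 unadjusted, Nos1 0.35, adjusted p = 0.0669).

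Of the genes tested in both fractions, 42 were higher in PMCA mice in both (5.29 for independent lists) and 11 were lower in both (1.32), and the folds correlated with r = 0.587 across 15470 genes, which are not independent replicates, from different libraries of the same mice. Input and IP of 1 mouse deviated together, so overlap and correlation can exceed those of independent lists without an effect of the pump.

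Whether the PMCA effect differed between IP and input was tested in 1 model over 16 libraries. Interneuron markers differed most firmly: the median difference of the effect, IP minus input, was -0.34 on the log2 scale, 5 of 13 passed (7 adjusted over the list alone), and Pvalb (-1.03, SE 0.22), Pthlh (-0.95, SE 0.18), the choline transporter Slc5a7 (-0.68, SE 0.13), Chat (-0.52, SE 0.084) and Nos1 (-0.47, SE 0.096) all had a lower effect in IP (n = 4 per group). For Nos1 the difference came more from input (0.35, adjusted p = 0.0669) than from IP (-0.12, adjusted p = 0.227), neither of which passed. Microglial markers (median 0.78, Fcrls 1.37, SE 0.28, and Itgam 1.25, SE 0.30) and nuclear noncoding RNA (0.92, Snhg11 1.12, Malat1 1.10, Meg3 1.03) had a higher effect in IP, 5 of 20 and 5 of 7 passing (6 and 5 adjusted over the list alone). Rpl22 fell more in IP than in input (-0.81, SE 0.12, adjusted p = 0.00384). The effect was also lower in IP for Spp1 (-2.21, SE 0.23, 0.000265), Vtn (-1.59, SE 0.17, 0.000265) and the growth factor Igf2 (-1.46, SE 0.19, 0.00168), which did not pass in input.

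Higher effects in IP were also found for Klk8 (2.55, SE 0.58), Gpr160 (2.25, SE 0.44), Rasal3 (2.21, SE 0.34, adjusted p = 0.00639), Milr1 (2.12, SE 0.52), Mndal (2.02, SE 0.39), Olfml3 (1.90, SE 0.27, 0.00353), Tifab (1.88, SE 0.38), Cd22 (1.86, SE 0.45), Mcmdc2 (1.79, SE 0.44) and Cd33 (1.67, SE 0.23, 0.00248). All of these lay lower in IP than in input in control mice, and all but Klk8 did in PMCA mice. Apart from Olfml3 (1.48), their control IP means lay between -3.88 (Milr1) and -1.22 (Cd33) log2 CPM, so these effects rest on low levels in IP. Lower effects were found for Cxcl9 (-2.19, SE 0.43), Dmrtb1 (-1.67, SE 0.39), Wfikkn1 (-1.57, SE 0.30), Pmaip1 (-1.46, SE 0.28), Col18a1 (-1.41, SE 0.24) and Mc4r (-1.30, SE 0.33). Mndal shares sequence with neighbouring genes. Mc4r did not pass with the animal as a block (adjusted p = 0.0582). No difference passed for Atp2b2 (0.21, adjusted p = 0.552), Gfap (0.23, 0.724), Slc1a2 (0.09, 0.871), Slc6a11 (-0.07, 0.853) or Itpr2 (-0.11, 0.784), nor for Kcnj10 (0.37, 0.172) until the animal was a block (0.0489).

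The test passed 339 of 16673 genes, 162 with a higher and 177 with a lower effect in IP, 43 and 29 of them by at least 2-fold. With total reads and no scaling factors the split was 120 to 235, and with the animal as a block 278 to 188 of 466. The count was 164 without control 1, 23 without control 2, 119 without control 3, 41 without PMCA 1, 36 without PMCA 2 and 54 without PMCA 3. Of 21 named calls, 7 held whichever animal was left out: Rpl22, Spp1, Vtn, Igf2, Cd33, Olfml3 and Rasal3. Camera called 8 lists. The interneuron list (adjusted p = 1.64e-07) kept its call with an estimated correlation (adjusted p = 0.0365) and by fry (0.00101). Nuclear noncoding RNA (1.49e-07, and 0.187 with an estimated correlation) was called by fry (0.00873), and microglia (7.73e-07, 0.426 with an estimated correlation) were not (0.0674).

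The neuron list was lower (median -0.27, 4 of 26 passing and 11 adjusted over the list alone, Nefh -0.74, Gad1 -0.60), with an adjusted p of 8.91e-10, and 0.426 with an estimated correlation. Ribosomal proteins (-0.20, 2 of 82 passing and 15 adjusted over the list alone, Rpl6 -0.37, Rps4x -0.41; 6.33e-14, and 0.767 with an estimated correlation) and the respiratory chain (-0.12, 0 of 78 passing, 10 at an unadjusted p under 0.05; 5.37e-05, and 0.982 with an estimated correlation) were lower too. The calls of the unfolded protein response (-0.06, Herpud1 -0.48, Asns -0.46; 0.0377, and 0.767 with an estimated correlation) and of glycolysis (-0.08, Gpi1 -0.29; 0.0377, and 0.871 with an estimated correlation) depended on single animals. The former was lost without control 3 (0.0648), control 4 (0.0991), PMCA 1 (0.066) or PMCA 3 (0.0758). The latter was lost without control 2 (0.198), control 3 (0.0789), control 4 (0.055) or PMCA 4 (0.2), and with the animal as a block (0.12). The astrocyte list had a median of 0.02 with 0 of 41 passing (4 at an unadjusted p under 0.05).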

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

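The tests of microglial markers, of a share of lysate RNA and of tagged ribosomes were chosen only after the results were seen. So were the comparison with genes of like span, the sex block and the fit without control 4 and PMCA 3. The other splits were not. The correction for gene span was set before its own outcome was seen, but after the medians of the lists in IP were known.

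Libraries far from the other 3 of their group were found in 35 of 444 groups of 4 values examined, where chance gives about 1 in 20. The control 4 input held 9 of them. Its scaling factor was 1.11, its microglia list lay at 6.25 log2 CPM and its clock genes at 6.16, and C1qb (7.50), Aqp4 (7.82), Rasal3 (3.27), Milr1 (1.34), Olfml3 (6.02) and Cd22 (1.96) stood apart. The PMCA 4 IP also held 9. Its neuron list lay at 7.53, microglia at 2.46, endothelial markers at 1.301 and the list of potassium, water and gap junctions at 8.69, with Havcr2 at 2.34, Sox9 at 7.94, Gpc4 at 4.96 and Cx3cr1 at 5.19. The control 1 IP stood apart in Sgca (2.36), Aqp4 (10.40), Cx3cr1 (0.999) and Dmrtb1 (-0.84).

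Other inputs stood apart in 1 to 3 values. These were Slc6a11 in control 1 (6.45), the astrocyte list in control 2 (6.66), Dthd1 in control 3 (-5.14), the glucocorticoid list in PMCA 1 (4.36), the oligodendrocyte list in PMCA 2 (7.14), the synapse-acting list (4.71), Snora74a (3.91) and Tyrobp (5.38) in PMCA 3, and the scaling factor (1.12) and Fn1 (4.10) in PMCA 4. Among IP libraries, Tfcp2l1 in PMCA 1 (6.99), the ependymal list in PMCA 2 (2.22) and Col18a1 in PMCA 3 (1.60) did.

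The PMCA effect differed between IP and input in 339 genes by limma's interaction term. Among named genes the effect was higher in IP for Klk8 (2.55), Gpr160 (2.25), Rasal3 (2.21), Milr1 (2.12), Mndal (2.02), Olfml3 (1.90), Tifab (1.88), Cd22 (1.86), Mcmdc2 (1.79) and Cd33 (1.67), all of which lay lower in IP than in input in control mice. The effect was lower in IP for Rpl22 (-0.81), Spp1 (-2.21), Cxcl9 (-2.19), Dmrtb1 (-1.67), Vtn (-1.59), Wfikkn1 (-1.57), Pmaip1 (-1.46), Igf2 (-1.46), Col18a1 (-1.41) and Mc4r (-1.30).

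Among the 35 splits of the 8 IP libraries into groups of 4, only the real one, 1 of 35, gave 3088 genes, and the highest of the others gave 0. Chance is therefore unlikely for that count, and 1 of 35 is the smallest share that these splits can give. The same held, 1 split of 35 and 0 as the highest other, for the 510 astrocyte-enriched genes and the 339 genes with different effects. These counts draw on the same IP libraries and are not separate support. For IP against input in control (12457) and PMCA mice (12551) the real split was also 1 of 35 with 0 as the highest other, but the libraries are paired by mouse, and the splits that part all 4 pairs, 7 besides the real one, are too few for a share under 0.05. In input 3 of 35 splits gave 72 genes or more, so chance cannot be excluded. Control 1 to 3 with PMCA 1 against the rest gave 773 genes and control 1 to 3 with PMCA 2 gave 456, which points to a structure of the samples. With the animal-number set as a block 868 genes passed with control 4 placed by its title and 32 with control 4 placed by its source name. With sex as a block it was 786, and 490 without control 4 and PMCA 3, the mice with more Xist than Ddx3y reads. Whether the sets or sex are that structure is open.

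Microglial markers rose in PMCA IP (median 0.88). Carry-over of lysate RNA into the PMCA precipitate may account for part of it. The test used 11 markers of other cell types that lay at least 3 lower (log2) in IP than in input in control mice. Their median was 0.64, 10 of them higher and 4 past the threshold, near the 0.51 that the share given by microglial markers predicts. All but Kcnj8 (mural) and Col3a1 (leptomeningeal) were endothelial markers, whose list was not called without PMCA 4, so other cell types were hardly covered. The 11 markers were chosen on the same control IP libraries that their folds were taken against. Low values there favour both, so the nearness of 0.64 to 0.51 is not an independent check of carry-over. Kcnj8 lay at -1.12 (predicted 0.32), and the mural list at 1.53 log2 CPM in control and 1.34 in PMCA IP. The rise of microglial markers did not rest on the PMCA 4 library, whose Cx3cr1 (5.19) stood apart. Without that library the median was 0.84 with 10 members past the threshold and a fry adjusted p of 0.011. More microglial RNA in the tissue cannot be told apart as a part of the cause. The input list rose by a median of 0.24, and the difference between fractions, 0.78, had a fry adjusted p of 0.0674. That rise in input is itself uncertain, since the level also followed the animal numbers. The list lay at 6.25 log2 CPM in control 4, above all 4 PMCA inputs (6.02 to 6.23), and at 5.77 to 5.84 in control 1 to 3. No list other than microglia held any of its 20 markers.

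Nuclear noncoding RNA rose and transcripts of ribosomal proteins and the respiratory chain fell in PMCA IP. In input, where only camera at the preset correlation called them, these lists moved the same way but less far. Mean levels in control and PMCA input were 8.27 and 8.50, 6.77 and 6.61, and 6.00 and 5.79 log2 CPM. For the respiratory chain they were 6.17 and 5.84 in IP. The input libraries overlapped between the groups: these lists lay at 8.41, 6.63 and 5.84 in control 4, against 8.35, 6.70 and 5.92 in PMCA 1. Camera at the preset correlation still called the ribosomal protein and respiratory chain lists with the number set as a block, in either placement. Whether the shift in input belongs to the treatment is therefore open. If it does, a cause that acts only in the precipitate cannot account for it. Whole-lysate RNA at the share the microglial markers give, 2.57%, predicts a rise of 0.21 for the nuclear list, and with it taken out the median was still 0.95 (fry adjusted p = 0.015), 6 of 7 members lying more than 2 SE above it. The span of a gene in the genome is argued against as the whole cause, while transcript length was not examined. With each library's mean trend with gene span taken out (14856 genes), which lowered the rank correlation of fold and span only from 0.108 to 0.070, the medians were 1.12, -0.41 and -0.36 (fry adjusted p = 0.00602, 0.00478 and 0.00602), and the 200 genes nearest in span to each member had medians of 0.0058, -0.059 and -0.054. Fewer tagged ribosomes in the precipitate, which could leave a larger share of nuclear or unspecifically bound RNA, cannot be told apart from an effect of the pump, such as an untested change of translation, because Rpl22 was lower in all 4 PMCA precipitates (-1.69) and so follows the treatment.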

How the results depend on the processing

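The microglial covariate, total reads, the sex block and leaving out control 4 and PMCA 3 as the animals with more Xist than Ddx3y reads were chosen after seeing the data. The cause of the changes given here was not tested. The microglial and purity covariates follow the treatment wholly or in part, so they can take out an effect of treatment itself. For PMCA against control in IP the count of 3088 became 4894 with all 16 libraries in 1 fit, 1699 with the number set as a block and control 4 placed by its source name, 1243 without control 4 and PMCA 3 (a fit on fewer samples, 1153 of them among the 3088), 1347 with the purity covariate (1066 shared) and 395 with the microglial covariate (281 shared), and 1710 to 3645 with 1 animal left out. In input the 72 genes became 43 without a filter, 47 with all 16 libraries, 868 and 32 with the number set as a block by title and by source name, 786 with the sex block, 490 without control 4 and PMCA 3, and 5 to 1350 with 1 animal left out, control 4 giving the highest. The 339 genes of the difference between fractions became 23 to 434 with 1 animal left out. The pairing by animal as a block gave 466 genes there (279 of them among the 339), and 12772 and 12733 for IP against input, and among the named genes and lists it changed no other call than those of Mc4r, Kcnj10 and glycolysis in the difference. The 510 astrocyte-enriched genes became 2.6e+02 with the purity covariate (81 higher and 176 lower), 278 with the microglial one, 236 at an enrichment of at least 2 and 1391 at any above 0, and 290 to 668 with 1 animal left out. IP against input ranged from 11411 to 12259 in control and 11479 to 12686 in PMCA mice. Camera's calls of 11, 13, 19 and 22 lists became 0 with an estimated correlation in the comparisons of IP, input, control and PMCA mice, and its 8 became 1 in the difference.

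These values changed sign, most of them near 0: with the microglial covariate Havcr2 (-0.13), Slc6a11 (0.13) and the A1 list (-0.51) in IP; Slc6a11 in input with control 4 placed by its source name (0.00049), and without control 1 (0.043) or PMCA 3 (0.024), with a range of -0.067 to 0.043; Mbp in control mice without control 1 (0.0037, range -0.36 to 0.0037) and in PMCA mice with total reads (-0.18); and in the difference, without control 3, Slc6a11 (0.019, range -0.16 to 0.019) and Itpr2 (0.0026, range -0.25 to 0.0026). Over named genes 2123 alternative values kept side and direction, 258 no longer passed, 20 newly passed and 9 turned. Over lists 1016 kept, 73 no longer passed and 1 turned. DESeq2 was not run here. Size factors by relative log expression changed no count by more than 1.5 times.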

Other observations

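The tests of unseen p53 target genes were written before their values were seen, and the test without members of other lists, the test of vector dose and the cortical markers were chosen after the result was seen.

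Markers of cortical glutamatergic neurons, chosen after their values were seen, varied between mice. Slc17a7, a vesicular glutamate transporter, lay at 4.49 log2 CPM in the input of control 2 and 4.51 in that of PMCA 2, and at 3.80 and 5.08 in their IP libraries. The PMCA 4 IP had 4.17 against 5.95 in its input, and all other libraries lay between 5.95 and 6.74. Tbr1, a cortical transcription factor, lay at 1.10, 1.22, 1.48 and 2.54 in the input and IP of control 2 and of PMCA 2. In PMCA 4 IP it was 1.76, and elsewhere 2.93 to 3.89.

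Targets of p53, a stress-induced transcription factor, were lower on balance in PMCA mice, and a weaker p53 response is offered as a hypothesis. Gdf15 (-2.91 in IP), Ckap2 (-1.98), Pmaip1 (-1.64), Psrc1 (-0.91), Eda2r (-0.89), Cdkn1a (-0.75), Phlda3 (-0.60), Aen (-0.54) and Ccng1 (-0.43) had drawn attention because they had fallen, and the single values of 30 further targets had not been looked at when the list of 39 was written. Of 28 unseen members tested, 23 lay below 0 in IP (median -0.28, 11 lower past the threshold such as Gtse1 -0.83, Mdm2 -0.62 and Plk2 -0.61, Ddb2 0.30 and Zmat3 0.23 above 0 without passing, fry p = 0.000122, camera p = 0.0188 with an estimated correlation), and 21 lay below 0 in input (median -0.14, 0 past the threshold, fry p = 0.0041, camera p = 0.0214 with an estimated correlation), which is consistent with a weaker p53 response in both fractions. Of these, 3 (Rps27l, Btg2 and Sesn2) belong to other lists whose results were known by then, and without them the fry p was 6.6e-05 in IP (25 members, 20 below 0, 9 lower past the threshold) and 0.00821 in input. A lower dose of the tagged ribosome vector may be behind it, and cannot be told apart from an effect of the pump, since Rpl22 was also lower in all 4 PMCA inputs (-0.88).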
